A study of Mus musculus with 4 samples.

How the data were processed

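LMPPs were sorted from mouse bone marrow, and their RNA was captured in 10x Genomics droplets and sequenced on a NextSeq 500, giving 1 library for each of the 4 groups (control, RBPJ uninduced, RBPJ 3 days induced, RBPJ 6 days induced). Doxycycline was injected into the abdomen at 2 mg/ml and then given at 1 mg/ml in the drinking water. The labels carry this treatment text for every library, so they do not say whether the control and uninduced mice received it. Seurat and the mm10 genome are named, per the submitters' processing notes, without role or version, and the aligner, the counting tool and the annotation were not given in the sources used here. The deposited matrices hold whole UMI counts for 27998 genes and 737280 barcodes per library, with no cell filter. A further deposited table per library holds log2 values, which the authors computed as log2 of the count divided by a size factor of the cell, plus 1. Multiplying back by 1 factor per cell gave whole counts equal to those of the matrix to within 1e-06 in every checked gene. Size factors averaged 1 within each library, so the log2 tables are not on a common scale, and they were used here only to define the cells.

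The cells were those whose barcodes stand in the authors' log2 tables, 2693, 2769, 1292 and 2129 in control, uninduced, 3-day and 6-day libraries, and their counts were read from the deposited count matrices. They held 90.6%, 93.6%, 91.5% and 90.5% of all UMIs. Genes were counted by identifier, and 121 genes share their symbol with another identifier. UMIs were summed over the cells of a library and scaled to CPM by the total. Ratios are log2 of (CPM + 1), folds are ratios of CPM, and both come with the levels they compare. Intervals at 95% are exact Poisson for levels, conditional exact for folds and exact binomial (Clopper-Pearson) for shares. No test was made across cells, because cells of 1 library are not replicates. No paired analysis was possible because each group has 1 library. The 6 comparisons between libraries, the 26 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later.

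Counts of genes used a minimum of 10 CPM in either library and 2-fold on the CPM + 1 scale. Genes named in a comparison were the 10 with the highest and the 10 with the lowest log2 ratio above that minimum, apart from sex-linked, haemoglobin and antigen receptor segment genes, the reversal genes, up to 2 members each way of each gene list, Rbpj and the core Notch targets. Reversal genes were at least 1.5-fold lower in uninduced than in control cells and at least 1.5-fold higher in both induced libraries than in uninduced cells, or the opposite, at 10 CPM or more in any library. List medians used members at 2 CPM or more in either library, with intervals from 1000 Poisson draws of the counts and a percentile among 10000 random lists matched on size and mean expression. The lists were Notch target genes, core Notch target genes, Notch pathway components, T lineage, lymphoid priming, B lineage, myeloid progenitor, mature neutrophil and monocyte, erythroid, megakaryocyte, stem cell, dendritic cell, NK and innate lymphoid, basophil, eosinophil and mast cell, bone marrow stroma and endothelium, S phase, G2 and M phase, mitochondrially encoded, nuclear oxidative phosphorylation, integrated stress response, dissociation and immediate early, interferon response, p53 and apoptosis, ribosomal protein, MHC class II and sex-linked genes. Some lists share members, as Ly6d stands on the lymphoid priming, B lineage and dendritic cell lists.

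Shares of cells with a UMI were taken after thinning each cell to 4700 UMIs, which left out 351, 676, 204 and 374 shallower cells in the same order. All cells were clustered together without batch correction by the Leiden method at resolution 1.0, with 15 neighbours, 30 principal components and 2000 variable genes, leaving out Rbpj, Notch target, cell cycle, ribosomal, mitochondrial, haemoglobin and sex-linked genes. Of 17 clusters 8 took a cell type name from marker lists, and the cells of 5 named for types outside the sorted progenitors are called other cell types. Scrublet, at an expected rate of 0.06, called 25 of 8883 cells (0.281%) doublets, so few that the caller cannot be taken to have worked, and doublets were kept. Barcodes with 10 to 100 UMIs served as a profile of RNA outside cells. A gene's end was called mostly shared when at least 50% of its 31-base words in the last 500 bases of its transcripts (GENCODE vM21, GRCm38) occurred in another gene, which held for 182 of 7333 genes (2.48%).

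The comparison was tested on simulated data drawn as Poisson counts from the mean profile of the 4 libraries at the depths of the uninduced and control libraries, with 40 genes set to each fold among 7061. All 40 genes at each of 2-fold, 4-fold, 0.5-fold and 0.25-fold passed 1.5-fold in the simulated direction, 6 of 40 at 1.5-fold did, and 0 of 6861 unchanged genes did. At the depths of the 6-day and 3-day libraries 39 of 40 at 0.5-fold and 1 of 6924 unchanged genes did. The draws hold counting error only, so they do not show how often differences between libraries or in cell makeup would pass. Of 100 random lists of 20 unchanged genes, 8% fell outside percentiles 2.5 to 97.5. The alternatives tried were an own cell filter (at least 1000 UMIs, 500 genes and under 10% mitochondrial UMIs), removal of called doublets, edgeR TMM and DESeq2 scaling, a pseudocount of 5 CPM, no list filter with 30 CPM for gene counts, the mean of single-cell CPM, thinned cells, cells without UMIs of 7 mitotic genes, and clustering at resolutions 0.5 and 1.5. Leaving out the cells of other cell types, and leaving out each gene's 10 highest cells, were added after the data were seen. Barcodes outside the authors' cell sets were not used in any comparison. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.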

Results

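Single-cell transcriptomes were measured by droplet sequencing in lymphoid-primed multipotent progenitors (LMPPs), early blood progenitors with lymphoid and myeloid potential, sorted by flow cytometry from the bone marrow of C57BL/6 mice. RBPJ is the DNA-binding protein through which activated Notch receptors switch on their target genes. The 4 libraries were 1 each from control mice, in which RBPJ was always present, from mice that lacked RBPJ (uninduced), and from such mice 3 and 6 days after doxycycline had switched RBPJ on. How many mice each library held, and whether the control and uninduced mice were also given doxycycline, was not clear from the labels. The authors' cell sets held 2693 control, 2769 uninduced, 1292 3-day and 2129 6-day cells. Their unique molecular identifiers (UMIs, 1 per captured transcript) summed to 23504158, 20952799, 10647894 and 17455692 in the same order. Median UMIs per cell were 7920 in control, 6774 in uninduced, 7642 in 3-day and 7353 in 6-day cells, and median genes per cell were 2362, 2047, 2184 and 2131. Levels are UMIs summed over the cells of a library, scaled to a common library total and given as CPM. With 1 library per group, no difference reported here has a replicate check, library batch and group cannot be told apart, and the 95% intervals in brackets after levels, folds and shares cover counting error only.

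Rbpj itself, the targeted gene (ENSMUSG00000039191; GRCm38 chromosome 5, 53466152 to 53657362, plus strand, protein coding), was present at 17.8 CPM (16.1 to 19.6) in control and 11.2 CPM (9.83 to 12.7) in uninduced cells, a ratio of 0.631 (0.535 to 0.742). It stood at 508 CPM (495 to 522) at 3 days and 485 CPM (474 to 495) at 6 days, 45.3-fold (39.7 to 51.8) and 43.2-fold (38.0 to 49.4) above uninduced cells and 28.6-fold and 27.3-fold above control. The order of the libraries matched their labels. Whether the sequenced 3' end lies inside the deleted part of Rbpj was not stated in the labels, so the transcripts counted in uninduced cells do not measure remaining RBPJ function. After each cell was thinned to 4700 UMIs, 8.54% of control (7.44 to 9.75), 4.25% of uninduced (3.43 to 5.21), 43.9% of 3-day (41.0 to 46.9) and 43.8% of 6-day cells (41.5 to 46.2) held a Rbpj UMI. Unthinned shares were 13.9%, 6.93%, 44.4% and 45.6%. No cell type is known to lack Rbpj in these mice, so no background share can be set for it. RNA outside cells, in barcodes of 10 to 100 UMIs, held Rbpj at 17.4, 4.30, 291 and 285 CPM, and how much of the shares came from free RNA was not measured. In the progenitor cluster marked by Ccr9 and Tmem158, looked at after the data were seen, Rbpj stood at 29.7 CPM (18.4 to 45.4) at 3 days and 47.9 CPM (32.7 to 67.6) at 6 days. These values argue against free RNA spread alike over all cells as the source of most of the Rbpj level in the induced libraries. In the few myeloid and megakaryocyte-erythroid-like cells of each library the thinned shares were 8.82%, 5%, 73.9% and 76.7%.

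The uninduced and control libraries were set side by side to ask which transcripts differed in LMPPs without RBPJ. Hes1, a transcriptional repressor and direct Notch target (ENSMUSG00000022528; chromosome 16, 30064384 to 30067796, plus strand, protein coding), was the gene with the lowest ratio, at 18.0 CPM (16.2 to 19.9) in uninduced against 89.7 CPM (85.9 to 93.6) in control cells, 0.201-fold (0.179 to 0.224). Dissociation and immediate early genes were higher as a group in uninduced cells, 11 of 22 by at least 1.5-fold. Hspa1a, an inducible HSP70 chaperone, stood at 56.5 against 10.8 CPM (5.21-fold, 4.55 to 5.99), and Atf3, a stress-induced transcription factor, at 48.9 against 11.8 CPM (4.13-fold, 3.62 to 4.73). Neutrophil genes were also higher, but their UMIs came from few cells. Among 7235 genes at 10 CPM or more in either library, 26 were at least 2-fold higher and 8 at least 2-fold lower in uninduced cells, counted by size and not by test, and 98.5% lay within 1.5-fold. Without the clusters of other cell types, 10 genes were 2-fold higher and 8 lower.

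Of the other 9 genes with the lowest ratios in uninduced cells, Dqx1 stood at 0.271-fold (0.217 to 0.336), with 63.2% of its control UMIs in 10 cells, and Dennd5b at 38.8 against 93.3 CPM (0.415-fold, 0.383 to 0.450). The long noncoding RNA 2610035D17Rik was at 15.1 against 30.4 CPM (0.497-fold, 0.434 to 0.568). Sag, which encodes a visual arrestin, was at 0.431-fold (0.352 to 0.525). The mitochondrial gene mt-Atp8 was at 147 against 310.0 CPM (0.475-fold, 0.455 to 0.495), and overlaps mt-Atp6, so its counts are uncertain. Gm10263 (0.432-fold, 0.396 to 0.470), the importin gene Kpna2 (0.434-fold, 0.370 to 0.509) and the nucleoside diphosphate kinase gene Nme2 (0.492-fold, 0.431 to 0.561) are uncertain too, because 77.0%, 65.4% and 98.9% of the sequence at their transcript ends was shared with other genes. Cks1brt, named as a retrotransposed copy of Cks1b, was at 0.391-fold (0.301 to 0.504) and is likewise uncertain, although the shared part of its end was 6.17%.

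Of 22 measured dissociation and immediate early genes, 11 were at least 1.5-fold higher and 0 lower in uninduced cells. The list's median log2 ratio was 0.58 (0.56 to 0.62), at percentile 100 of 10000 random lists matched on size and expression, given as a description of these libraries. Klf2 and Klf6, zinc finger transcription factors, were among them. Interferon response genes had a median of 0.20 (0.18 to 0.28) at percentile 100, with 2 of 26 1.5-fold higher, and the antiviral ubiquitin-like gene Isg15 at 1.45-fold (1.31 to 1.59). MHC class II genes had a median of 0.20 (0.13 to 0.29) at percentile 100, led by the invariant chain gene Cd74 at 1.40-fold (1.33 to 1.47), and none of 8 reached 1.5-fold. In uninduced cells 10 cells held 23.5% of the Cd74 UMIs. Without the clusters of other cell types the list median was 0.13 over the same genes and the log2 ratio of Cd74 was 0.22. The progenitor cluster marked by Ccr9 and Tmem158, with Cd74 also among its markers, held 284 of 2769 uninduced and 122 of 2693 control cells. Whether this makeup moved the list was not tested. G2 and M phase genes were lower as a group, with a median of -0.22 (-0.26 to -0.18) at percentile 0, none of 33 reaching 1.5-fold on the CPM + 1 scale used for all counts, the mitotic kinase gene Ttk at 0.652-fold (0.557 to 0.764) and the cyclin gene Ccnb1 at 0.743-fold (0.681 to 0.810).

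Of 15 measured mature neutrophil and monocyte genes, 12 were 1.5-fold higher in uninduced cells, and the list median was 1.40 (1.26 to 1.56) at percentile 100. Among them were the granule protein genes Ngp (4.57-fold, 4.34 to 4.80), Camp (4.48-fold, 4.28 to 4.68), Lcn2 (4.13-fold, 3.73 to 4.59) and Ltf (3.77-fold, 3.12 to 4.57), the calprotectin genes S100a8 (3.34-fold, 3.27 to 3.41) and S100a9 (3.43-fold, 3.33 to 3.54), and Chil3 (4.06-fold, 3.29 to 5.05). Elane, the neutrophil elastase gene and a member of the myeloid progenitor list, was at 10.45 against 1.79 CPM (5.85-fold, 4.19 to 8.34). In uninduced cells 10 cells held 57.4% of the S100a8 UMIs and 97.7% of the Elane UMIs, and in control cells 97.9% and 100%. Without the clusters of other cell types the list median was 0.10 and the log2 ratios of Chil3 and Elane were -0.15 and 0.00. Erythroid genes had a median of 0.77 (0.56 to 1.02) over 12 genes and 0.07 without those clusters. Of its haemoglobin members Hba-a1 stood at 174 against 32.5 CPM, with 98.4% of the uninduced UMIs in 10 cells, and Hbb-bs at 224 against 39.8 CPM. Both are uncertain, since 94.8% and 57.3% of their ends are shared with sister genes.

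Hes1 was the only Notch target gene at least 1.5-fold lower in uninduced cells. The median over 16 measured Notch target genes was -0.05 (-0.11 to 0.05) at percentile 79.1, with 2 1.5-fold higher (Cd28 and Nrarp) and 1 lower, and that over 5 core targets was 0.09 (-0.18 to 0.28) at percentile 96.5. Of the other core targets Hes5 stood at 5.01 against 4.64 CPM, Nrarp at 6.63 against 3.87 and Ptcra at 4.20 against 3.66, while Hey1, Heyl, Dtx1, Notch3 and Il2ra were under 2 CPM in both libraries. The receptor gene Notch1 was at 0.906-fold (0.835 to 0.983), the fringe glycosyltransferase gene Lfng at 0.682-fold (0.589 to 0.788), and Cd28, a T cell costimulatory receptor gene (ENSMUSG00000026012; chromosome 1, 60716800 to 60773359, plus strand, protein coding), at 20.1 against 8.89 CPM (2.27-fold, 1.91 to 2.69). Notch pathway components had a median of -0.14 (-0.20 to -0.07) at percentile 8.60, with Rbpj the only one of 26 at 1.5-fold or more either way. Lymphoid priming genes had a median of -0.10 (-0.15 to -0.07) at percentile 4.20. Within that list Il7r, the interleukin 7 receptor, was at 0.677-fold (0.595 to 0.769) and Ly6d, a surface marker of B-biased lymphoid progenitors, at 2.10-fold (1.82 to 2.43). Progenitor clusters marked by Il7r and Ly6d held 58 and 119 of 2769 uninduced against 107 and 209 of 2693 control cells. Within the smaller Il7r stood at 87.9 CPM (66.8 to 114) against 106.7 CPM (89.3 to 127). Within the larger it stood at 68.0 CPM (51.6 to 87.9) against 63.8 CPM (51.8 to 77.8), and both pairs of intervals overlap. In the cluster marked by Ccr9 and Tmem158 it stood at 2.38 CPM (0.492 to 6.97) against 17.6 CPM (8.44 to 32.4). T lineage genes had a median of -0.16 (-0.25 to -0.04) and B lineage genes of 0.14 (0.07 to 0.32), at percentiles 11.7 and 99.9. In the B lineage list 5 of 12 genes were 1.5-fold higher. Early B-like cells, counted in a small cluster led by Vpreb3 and Cd79a, numbered 11 in uninduced against 5 in control. The larger clusters marked by Il7r and Ly6d, also named common lymphoid or early B-like and kept as progenitors, held fewer uninduced than control cells. Without other cell types the B lineage median was 0.06 over the same genes and -0.13 with members filtered anew.

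The remaining lists had medians within 0.1 of 0 in uninduced against control cells, where all genes compared had a median of -0.07. TMM and DESeq2 scaling shift that median by up to 0.0780, so no direction is read from these lists, although dendritic cell (percentile 99.8), integrated stress response (99.4), stem cell (99.2) and megakaryocyte genes (98.3) lay above the central 95% of random lists. Progenitor and lineage lists gave 0.03 for stem cell genes, -0.03 for myeloid progenitor genes, 0.07 for megakaryocyte genes, 0.07 for dendritic cell genes, -0.04 for NK and innate lymphoid genes, -0.07 for basophil, eosinophil and mast cell genes, and 0.09 for bone marrow stroma and endothelium genes. Process lists gave -0.06 for S phase genes, -0.06 for mitochondrially encoded genes, 0.01 for nuclear oxidative phosphorylation genes, 0.07 for integrated stress response genes, 0.00 for p53 and apoptosis genes, 0.02 for ribosomal protein genes and -0.05 for sex-linked genes.

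The 3-day and uninduced libraries were compared to ask what differed shortly after RBPJ was switched on. Hes1 was higher at 3 days, at 43.5 CPM (39.6 to 47.6) against 18.0 CPM, 2.42-fold (2.10 to 2.78), and stood at 0.485 (0.437 to 0.536) of its control level. After Rbpj, the highest ratios were those of Hspa1a, Hspb1 and Hspa1b, which encode heat shock proteins. Hspa1a was at 448 against 56.5 CPM (7.93-fold, 7.44 to 8.46), its near copy Hspa1b at 57.2 against 8.54 CPM (6.69-fold, 5.66 to 7.95), the small heat shock protein gene Hspb1 at 13.7 against 0.955 CPM (14.4-fold, 8.97 to 24.2) and Hsph1, an HSP110 chaperone gene, at 36.1 against 12.7 CPM (2.83-fold, 2.41 to 3.32). RNA outside cells, in barcodes of 10 to 100 UMIs, held Hspa1a at 637 CPM (552 to 731) at 3 days against 75.3 CPM (52.4 to 105) in uninduced. How much of its level in cells came from free RNA was not measured. Socs3, a feedback inhibitor of cytokine signalling, had the lowest ratio outside the haemoglobins, at 28.1 against 63.6 CPM (0.442-fold, 0.388 to 0.501). Of 7082 genes, 10 were at least 2-fold higher and 8 lower at 3 days, and 98.7% lay within 1.5-fold. Without the clusters of other cell types the counts were 8 and 5.

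The coding sequences of Hspa1a and Hspa1b are nearly identical, but 2.15% of the Hspa1b transcript end and none of the Hspa1a end was shared with another gene. Further genes with high ratios at 3 days were the chemokine gene Ccl5 (2.28-fold, 2.05 to 2.53, 76.3% of its UMIs in 10 cells), Gm28707 (2.25-fold, 1.72 to 2.97), and Elane (4.56-fold, 3.89 to 5.37) and Chil3 (2.57-fold, 2.25 to 2.93), for which 10 cells held 98.8% and 82.2% of the UMIs. The orphan nuclear receptor gene Nr4a1 was lower at 3 days, at 99.5 against 207 CPM (0.481-fold, 0.450 to 0.515), as were its relative Nr4a2 (0.511-fold, 0.419 to 0.620), the phosphatase gene Dusp5 (0.496-fold, 0.446 to 0.551), the chemokine gene Ccl3 (0.503-fold, 0.484 to 0.523) and the angiogenic factor gene Vegfa (0.471-fold, 0.345 to 0.633). The anion channel gene Lrrc8a stood at 0.443-fold (0.334 to 0.581), Evi2a at 0.515-fold (0.430 to 0.613), Ly6d at 0.469-fold (0.384 to 0.568) and Cd74 at 0.534-fold (0.496 to 0.575). Cd28 was at 11.3 against 20.1 CPM (0.560-fold, 0.453 to 0.687) and the receptor gene Notch2 at 18.8 against 31.5 CPM (0.595-fold, 0.506 to 0.698). The progenitor cluster led by Notch2 held 45 of 1292 3-day and 207 of 2769 uninduced cells. Whether this makeup moved the Notch2 ratio was not tested.

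By group, MHC class II genes were lower at 3 days, with a median log2 ratio of -0.38 (-0.55 to -0.27) at percentile 0 and 3 of 8 at least 1.5-fold lower, H2-Eb1 at 0.555-fold (0.482 to 0.638) among them. Stem cell genes had a median of -0.33 (-0.41 to -0.18) at percentile 0, with 3 of 20 1.5-fold lower, the transcriptional repressor gene Gfi1b at 0.624-fold (0.466 to 0.827) among them. The stem cell-like cluster held 150 of 1292 3-day and 541 of 2769 uninduced cells. Dendritic cell genes had a median of -0.22 (-0.32 to -0.11). Cell cycle genes were slightly higher, with medians of 0.12 (0.06 to 0.14) for S phase and 0.15 (0.08 to 0.18) for G2 and M phase genes, and Ccnb1 at 1.52-fold (1.37 to 1.69). Of the S phase genes 0 of 30 were 1.5-fold higher, and of the G2 and M phase genes 1 of 33, Ccnb1. The dissociation and immediate early list had a median of 0.00 (-0.02 to 0.07), with 4 of 22 genes 1.5-fold higher, the heat shock genes Hspa1a, Hspa1b, Dnajb1 and Hsp90aa1, and 2 lower. Over Notch target genes the median was -0.16 (-0.28 to -0.04), Hes1 was the only one 1.5-fold higher, and 3 of 16 were 1.5-fold lower, the cell cycle inhibitor gene Cdkn1a at 0.653-fold (0.594 to 0.717) among them. That median was -0.08 over the same genes without other cell types, -0.0261 in thinned cells and 0.00 without a list filter. Mature neutrophil and monocyte genes had a median of 0.40 (0.30 to 0.54) and erythroid genes of -1.09 (-1.30 to -0.88). With 10 cells removed per gene the neutrophil median was -0.62. Without other cell types the medians over the same genes were 0.43 for neutrophil and 0.03 for erythroid genes.

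The 6-day and uninduced libraries were compared to ask the same after a longer induction. Hes1 was at 129 CPM (124 to 135), 7.19-fold (6.44 to 8.04) its uninduced level and 1.44-fold (1.36 to 1.53) its control level. Ebf1, a transcription factor that specifies B cells, was at 21.4 against 9.88 CPM (2.17-fold, 1.83 to 2.58), and Il7r at 32.4 against 18.5 CPM (1.75-fold, 1.54 to 2.00). The progenitor clusters marked by Il7r and Ly6d held 84 and 186 of 2129 6-day against 58 and 119 of 2769 uninduced cells. Within the smaller Il7r stood at 97.4 CPM (78.9 to 119) against 87.9 CPM (66.8 to 114). Within the larger it stood at 79.5 CPM (65.1 to 96.2) against 68.0 CPM (51.6 to 87.9), and both pairs of intervals overlap. In the cluster led by mitotic genes it stood at 59.6 CPM (52.0 to 68.0) against 34.3 CPM (28.6 to 40.7). Immediate early genes were lower at 6 days. Klf2 stood at 186 against 567 CPM (0.329-fold, 0.316 to 0.342), Klf6 at 109.8 against 328 CPM (0.335-fold, 0.318 to 0.352), Klf4 at 0.444-fold (0.404 to 0.488), the AP-1 genes Fos and Fosb at 0.493-fold (0.484 to 0.503) and 0.484-fold (0.460 to 0.509), Atf3 at 0.490-fold (0.436 to 0.550) and Hspa1a at 0.335-fold (0.295 to 0.378). Of 7097 genes, 8 were at least 2-fold higher and 6 lower at 6 days, and 99.0% lay within 1.5-fold. Without the clusters of other cell types the counts were 5 and 7.

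Pf4, platelet factor 4, was at 122 against 2.29 CPM (53.2-fold, 40.01 to 72.4), but a single cell held 98.3% of its 6-day UMIs and its log2 ratio without the clusters of other cell types was 0.10. Retnlg (4.96-fold, 3.89 to 6.38) and Elane (2.23-fold, 1.89 to 2.64) likewise had 89.8% and 99.0% of their 6-day UMIs in 10 cells. Dqx1 was at 2.35-fold (1.85 to 3.01), Mgst2, a microsomal glutathione transferase gene, at 1.97-fold (1.74 to 2.24), mt-Atp8 at 2.04-fold (1.95 to 2.13) and Nme2 at 1.99-fold (1.73 to 2.29), with the uncertainty over the counts of mt-Atp8 and Nme2 given above. Cd28 was lower at 6 days, at 9.97 against 20.1 CPM (0.495-fold, 0.412 to 0.592), as were the noncoding Gm26532 (0.515-fold, 0.445 to 0.595) and H2-Eb1 (0.542-fold, 0.482 to 0.610).

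Lymphoid lists were higher at 6 days than in uninduced cells. The clusters marked by Il7r and Ly6d also held more of the 6-day cells, at 84 and 186 of 2129 against 58 and 119 of 2769. Whether this makeup moved the lists was not tested. Lymphoid priming genes had a median of 0.12 (0.08 to 0.17) with 4 of 27 at least 1.5-fold higher, namely Ebf1, Il7r and the recombinase genes Rag1 and Rag2, the last at 1.59-fold (1.30 to 1.93). T lineage genes had a median of 0.36 (0.15 to 0.48) over 13 genes and B lineage genes of 0.44 (0.19 to 0.56) over 13. All 3 lay at percentile 100 of random lists, and without the clusters of other cell types their medians were 0.15, 0.34 and 0.12. In the T lineage list only Rag1 and Rag2 were 1.5-fold higher, and Cd28 was 1.5-fold lower. The 3 lists share Rag1 and Rag2, so their medians are not separate evidence. Dissociation and immediate early genes had a median of -0.50 (-0.56 to -0.46) at percentile 0, with 10 of 22 1.5-fold lower and 0 higher. Interferon response genes (-0.21 (-0.25 to -0.13)), MHC class II genes (-0.31 (-0.43 to -0.25)) and stem cell genes (-0.19 (-0.24 to -0.12)) were also lower, with Hlf, a stem cell transcription factor gene, at 0.706-fold (0.649 to 0.768). Of these lists 3 of 26, 2 of 8 and 0 of 20 members were 1.5-fold lower. Mitochondrially encoded genes had a median of 0.17 (0.16 to 0.21), with mt-Atp8, mt-Nd3 and mt-Nd4l 1.5-fold higher, all 3 uncertain because their ends overlap or are shared with other genes. For Notch target genes the median was 0.06 (-0.04 to 0.12) and for core targets 0.10 (-0.01 to 0.37), Hes1 being the only member of either 1.5-fold higher.

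Genes that differed one way without RBPJ and the opposite way after induction were counted next. Of 7340 genes at 10 CPM or more in any library, 55 were at least 1.5-fold lower in uninduced than in control cells, and 3 of these were 1.5-fold higher again at both 3 and 6 days, against 0.0525 for independent lists. They were Hes1, 2610035D17Rik (ENSMUSG00000087259; chromosome 11, 113043895 to 113201838, minus strand, a long intergenic noncoding RNA gene) and Rbpj. Rbpj is the targeted gene, so its rise on induction was set by the design and its place in the count is no support. Levels of 2610035D17Rik were 30.4 CPM (28.2 to 32.7) in control, 15.1 (13.5 to 16.9) in uninduced, 28.6 (25.4 to 31.9) in 3-day and 29.6 (27.1 to 32.2) in 6-day cells. In the other direction 58 genes were 1.5-fold higher in uninduced cells and 1 was lower again at both times, against 0.0237 for independent lists. That gene was Cd28, at 8.89 (7.73 to 10.2), 20.1 (18.3 to 22.2), 11.3 (9.34 to 13.5) and 9.97 CPM (8.54 to 11.6) in the same order. Both steps share the uninduced library, which independent lists do not allow for. Of the lower genes 30 were 1.5-fold higher again at 6 days alone and 0 at 3 days alone, and of the higher genes 15 were lower again at 6 days alone and 11 at 3 days alone. These counts depend on the setting. The reversal genes lower without RBPJ numbered 5 in thinned cells and 6 in cells without mitotic gene UMIs, and those higher without RBPJ 3 and 2, or 0 at a minimum of 30 CPM.

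**Figure D1:**
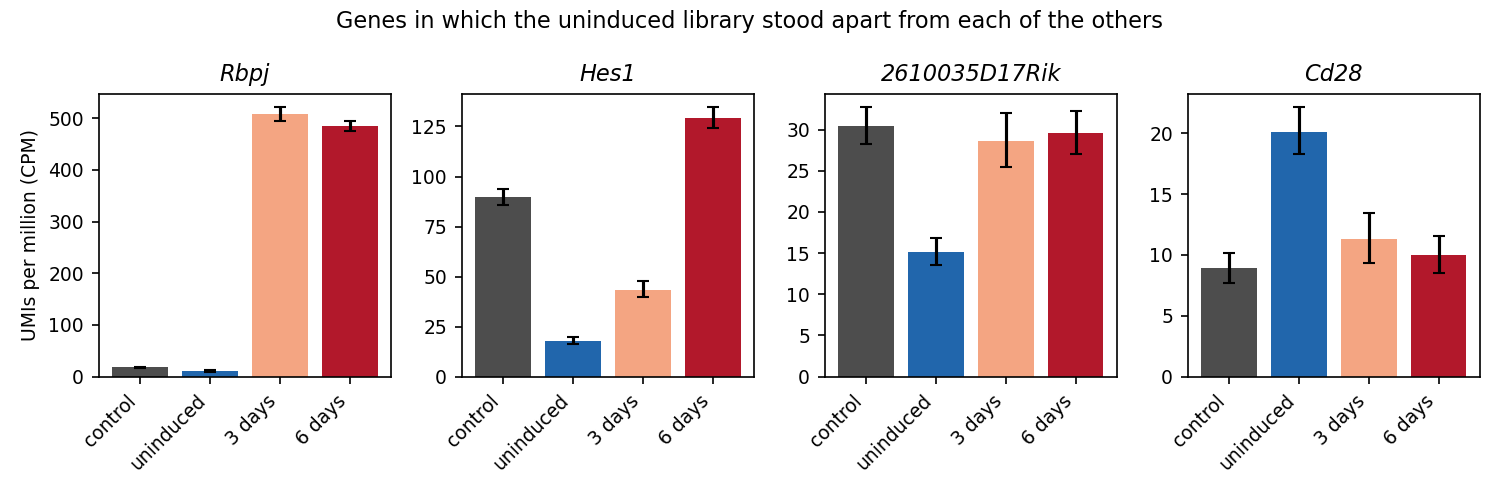
Levels of Hes1, 2610035D17Rik, Rbpj and Cd28 in the 4 libraries, in CPM on a linear axis in each panel, with 95% Poisson intervals of the summed UMIs that cover counting error only. Hes1 stands at 89.7, 18.0, 43.5 and 129 CPM in control, uninduced, 3-day and 6-day cells, and Cd28 is highest in uninduced cells at 20.1 CPM.

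The Hes1 order was also seen within cell clusters. After thinning to 4700 UMIs, 18.4% of control (16.8 to 19.99), 5.83% of uninduced (4.86 to 6.92), 10.0% of 3-day (8.30 to 12.0) and 24.4% of 6-day cells (22.4 to 26.5) held a Hes1 UMI, and unthinned shares were 24.5%, 8.16%, 14.1% and 30.6%. In myeloid and megakaryocyte-erythroid-like cells, taken as background, the thinned shares were 1 of 34 control, 1 of 60 uninduced, 0 of 23 3-day and 0 of 43 6-day cells. The intervals of these shares reach 15.3%, 8.94%, 14.8% and 8.22%. By share, the uninduced and 3-day cells are thus not told apart from background at this number of cells. By unthinned level, granulocyte-monocyte progenitor-like cells held 0 Hes1 UMIs, with upper limits of 7.74 CPM in uninduced and 36.0 CPM at 3 days. Both lie below the library levels of 18.0 and 43.5 CPM. Upper limits for neutrophil-like cells were 34.5 and 33.0 CPM, and for megakaryocyte-erythroid-like cells 50.5 and 136 CPM, of which only the 33.0 CPM lies below its library level. Before thinning, the median depth of the thinned cells was 8676, 8070, 8472 and 8312 UMIs, and that of the background cells 13675, 12084, 7536 and 10064. In each of 6 clusters with at least 50 cells in every library, a minimum set after the data were seen, Hes1 was lower in uninduced than in control cells, at 0.114 to 0.334-fold. It was higher at 3 days than in uninduced cells in 6 of 6 (1.05 to 3.82-fold, intervals apart in 5) and at 6 days in 6 (5.45 to 8.71-fold). In the cluster led by Notch2, left out with 45 3-day cells, Hes1 was lower at 3 days, at 3.55 CPM (0.0899 to 19.8, 1 UMI) against 8.59 CPM (4.44 to 15.01, 12 UMIs) in uninduced cells, intervals that overlap. The 6-day level was above the 3-day level in 6 of 6 clusters and above control in 5, with intervals apart from control in 4 of the 5. The exception was the cluster marked by Ccr9 and Tmem158, at 0.676-fold, also with intervals apart. In the stem cell-like cluster Hes1 stood at 156, 26.1, 69.4 and 166 CPM.

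**Figure D2:**
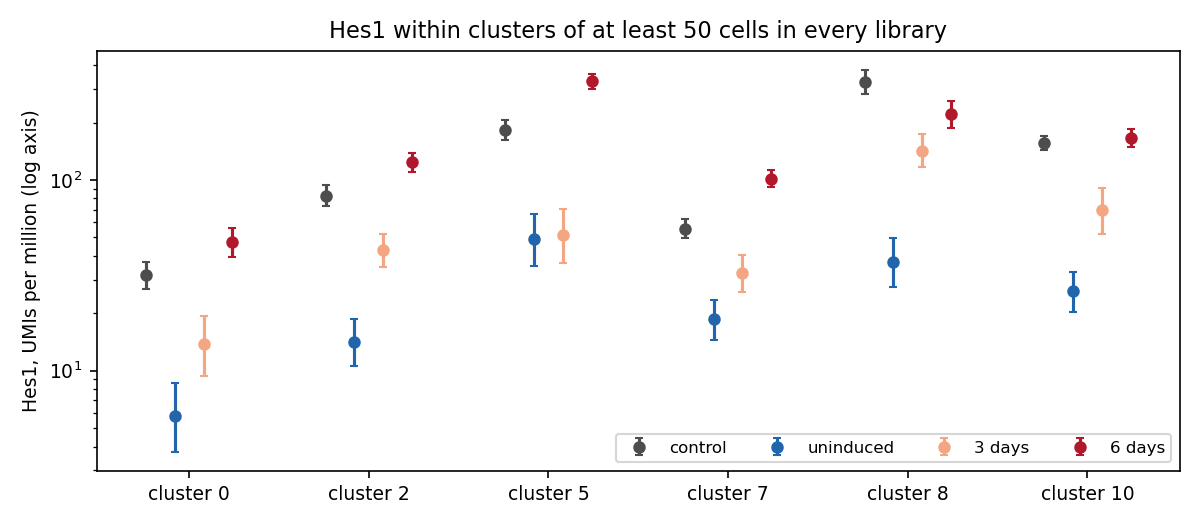
Hes1 level in CPM, with 95% Poisson intervals, in the 4 libraries within each of 6 clusters of at least 50 cells per library. Uninduced cells lie below control in every cluster shown, at 0.114 to 0.334-fold, and 6-day cells lie above 3-day cells in every one, at 1.55 to 6.35-fold.

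Longer against shorter induction was compared directly. Hes1 was 2.97-fold (2.69 to 3.29) higher at 6 than at 3 days, while Rbpj was at 0.954-fold (0.922 to 0.987). Lymphoid genes were higher at 6 days, with Il7r at 32.4 against 15.6 CPM (2.08-fold, 1.75 to 2.49), Ly6d at 28.5 against 12.2 CPM (2.33-fold, 1.92 to 2.85), Ebf1 at 2.00-fold (1.62 to 2.49) and Ccr9, a chemokine receptor gene of thymus-seeding cells, at 1.84-fold (1.47 to 2.32). Their list medians were 0.18 (0.12 to 0.26) for lymphoid priming, 0.57 (0.28 to 0.79) for B lineage and 0.24 (0.08 to 0.41) for T lineage genes. The progenitor clusters marked by Il7r and Ly6d held 84 and 186 of 2129 6-day against 13 and 100 of 1292 3-day cells. Other genes higher at 6 days were Socs2, a suppressor of cytokine signalling (3.06-fold, 2.22 to 4.30), Vegfa (2.83-fold, 2.11 to 3.85), Ppp1r16b (2.49-fold, 1.79 to 3.54), Ccl3 (2.14-fold, 2.06 to 2.23) and Lrrc8a (2.29-fold, 1.74 to 3.05). Dynlt1c was at 2.27-fold (1.75 to 2.97) but shares 72.5% of its transcript end with other genes. Hspa1a was lower at 6 days, at 18.9 against 448 CPM (0.0422-fold, 0.0376 to 0.0472), as were Hspa1b at 0.0611-fold (0.0462 to 0.0796), Dnajb1, an HSP40 cochaperone, at 0.381-fold (0.363 to 0.401) and Hsph1 at 0.410-fold (0.349 to 0.481). Hspb1 had 1 UMI at 6 days and 146 at 3 days, a ratio of 0.00418-fold (0.000105 to 0.0236). Klf6 (0.296-fold, 0.280 to 0.313), Klf2 (0.337-fold, 0.323 to 0.352), Cdk5rap1 (0.251-fold, 0.175 to 0.356), Cxcl10 (0.378-fold, 0.284 to 0.501) and Ccl5 (0.314-fold, 0.277 to 0.355) were lower too, and 12 of 22 dissociation and immediate early genes were 1.5-fold lower and 2 higher. Of 7118 genes, 18 were 2-fold higher and 14 lower, or 12 and 13 without the clusters of other cell types, where Pf4 and Retnlg had log2 ratios of -0.06 and -0.31.

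Comparisons with control asked what still differed after induction. At 3 days 36 of 7255 genes were 2-fold higher and 13 lower than in control, and at 6 days 24 of 7235 were higher and 0 lower. Without the clusters of other cell types the 3-day counts were 24 and 10 and the 6-day counts 6 and 0. Hspa1a (41.3-fold, 36.4 to 47.0) and Hspa1b (24.0-fold, 18.2 to 32.2) were far higher at 3 days, whereas Dennd5b (0.350-fold, 0.312 to 0.392), Socs3 (0.390-fold, 0.344 to 0.441), Nr4a2 (0.452-fold, 0.373 to 0.546), the interferon-induced GTPase gene Irgm1 (0.470-fold, 0.386 to 0.569) and Hes1 (0.485-fold, 0.437 to 0.536) were lower. Dqx1 (0.320-fold, 0.241 to 0.417), Gm26737 (0.301-fold, 0.214 to 0.413) and Gm13075 (0.345-fold, 0.244 to 0.477) were lower as well but had 63.2%, 77.4% and 49.8% of their control UMIs in 10 cells, and Gm10263 and Rps27rt share most of their transcript ends with other genes. At 6 days Cxcl2, a neutrophil-attracting chemokine gene, was at 136 against 24.3 CPM (5.60-fold, 5.11 to 6.15). Among the lowest 6-day ratios were those of the mucin gene Muc13 (0.537-fold, 0.461 to 0.624), the lipoprotein receptor gene Vldlr (0.575-fold, 0.483 to 0.682), P3h3 (0.602-fold, 0.482 to 0.748), Gm15658 (0.612-fold, 0.505 to 0.740), Clnk (0.619-fold, 0.508 to 0.751), Mboat1 (0.619-fold, 0.494 to 0.772), Dennd5b (0.649-fold, 0.603 to 0.699), Dqx1 (0.638-fold, 0.538 to 0.754) and the organic cation transporter gene Slc22a3 (0.646-fold, 0.563 to 0.739). Elane was at 26.7-fold (19.5 to 37.5) its control level at 3 days and 13.05-fold (9.48 to 18.4) at 6 days, and Ly6c2 at 7.74-fold (6.11 to 9.88) and 5.16-fold (4.09 to 6.58), though 56.6% of the Ly6c2 end is shared. Both stand on the myeloid progenitor list, whose medians were 0.10 (0.05 to 0.16) and -0.07 (-0.12 to -0.02). A single cell held 81.0% of the Elane UMIs in control, 55.5% at 3 days and 30.2% at 6 days. Of 16 mature neutrophil and monocyte genes 13 were 1.5-fold higher than in control at 3 days, and 15 of 18 at 6 days, with Ltf at 7.44-fold (6.16 to 9.03) and 4.67-fold (3.87 to 5.67) and S100a8 at 3.96-fold (3.87 to 4.05) and 2.79-fold (2.73 to 2.85). Their list median was 1.95 (1.75 to 1.99) at 3 days and 1.495 (1.44 to 1.57) at 6 days, and 0.30 and 0.10 without other cell types.

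**Figure D3:**
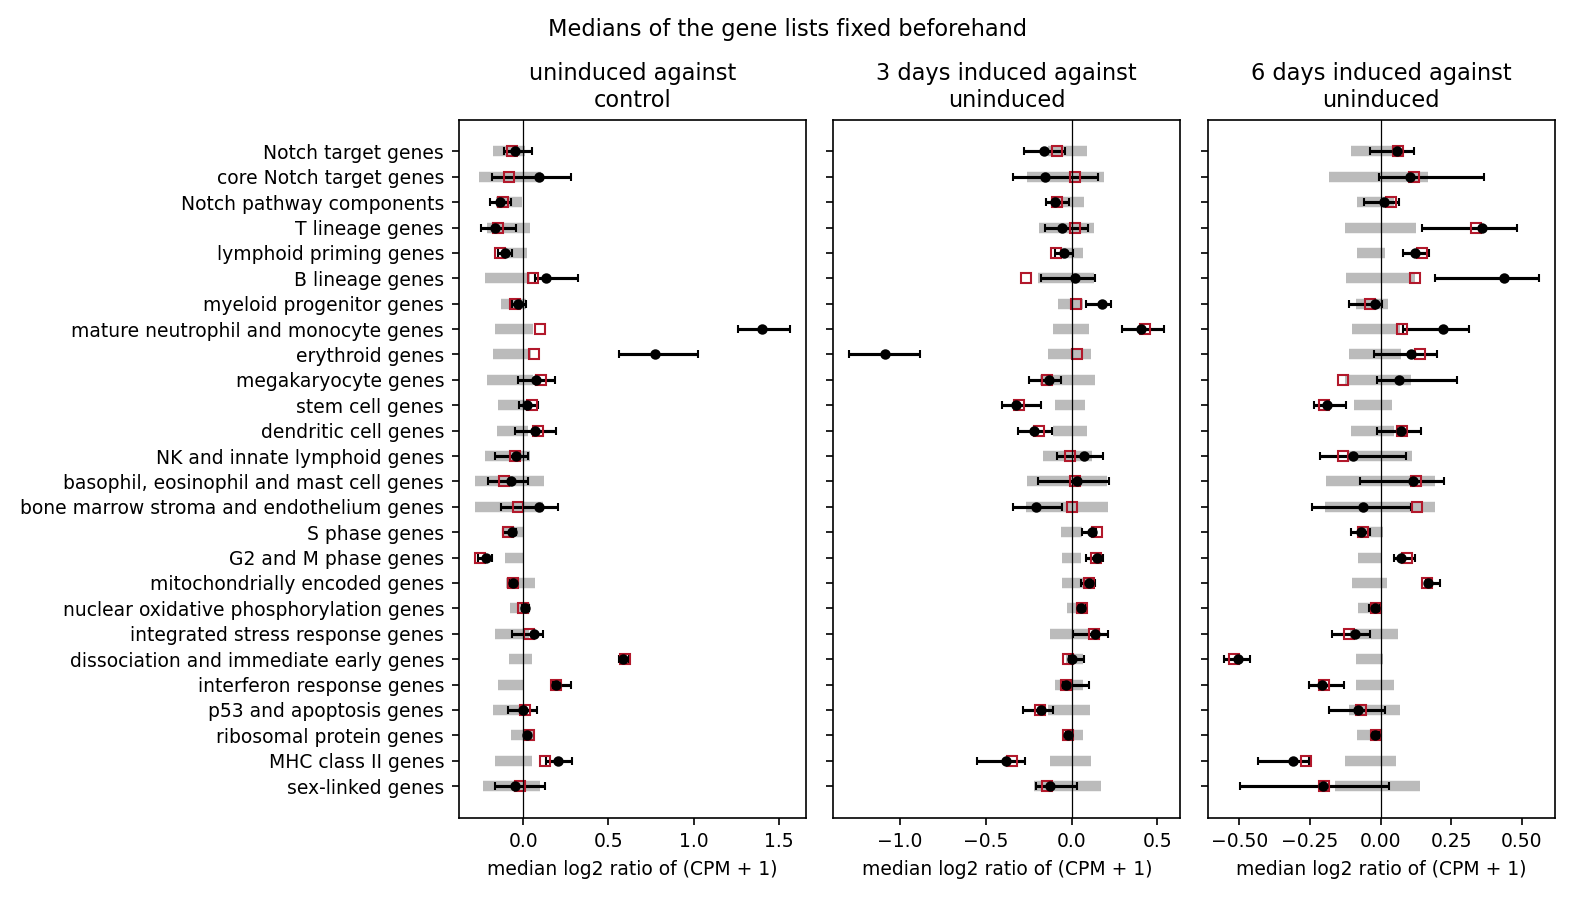
Median log2 ratio of (CPM + 1) of the 26 gene lists in 3 comparisons (filled points, with bars for the 95% range over 1000 Poisson draws), the same median without other cell types (open squares) and the central 95% of medians of random lists (grey bands). Dissociation and immediate early genes have medians of 0.58 in uninduced against control cells and -0.50 in 6-day against uninduced cells.

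Cells of other types made up a small part of each sorted library. Clustering gave 17 clusters, of which 5 carried markers of other cell types and held 45 of 2693 (1.67%, 1.22 to 2.23) control, 84 of 2769 (3.03%, 2.43 to 3.74) uninduced, 34 of 1292 (2.63%, 1.83 to 3.66) 3-day and 79 of 2129 (3.71%, 2.95 to 4.60) 6-day cells. Neutrophil or monocyte-like cells, led by S100a8, S100a9 and Camp, numbered 7 of 2693 (0.260%, 0.105 to 0.535) in control, 25 of 2769 (0.903%, 0.585 to 1.33) in uninduced, 14 of 1292 (1.08%, 0.594 to 1.81) in 3-day and 24 of 2129 (1.13%, 0.724 to 1.67) in 6-day cells. Megakaryocyte-erythroid-like cells, led by haemoglobin genes and Pf4, numbered 4, 8, 4 and 10. Granulocyte-monocyte progenitor-like cells, with Elane, Ctsg and Ly6c2, numbered 29, 39, 12 and 28, and early B-like cells with Vpreb3, Cd79a and Igll1 numbered 5, 11, 3 and 13. The neutrophil-like cluster held 97.7% of control, 98.7% of uninduced, 97.0% of 3-day and 97.4% of 6-day S100a8 UMIs. The haemoglobin gene Hba-a1 stood at 32.5, 174, 3.66 and 167 CPM. At clustering resolution 0.5 other cell types made up 0.594%, 1.55%, 1.70% and 2.16%, at resolution 1.5 3.56%, 3.86%, 4.72% and 4.70%, where the control and uninduced intervals overlap, and with called doublets removed 4.87%, 5.35%, 5.61% and 5.62%. With called doublets removed the granulocyte-monocyte progenitor-like cells numbered 114, 103, 50 and 67, so their number depends on the clustering. Shares of sorted populations depend on the gate, whose limits were not given in the labels.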

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

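The tests of shared reads, of cells without a mitotic gene UMI and of progenitor clusters were chosen before their results were seen, and the other tests in this part only afterwards.

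Hspa1a had a log2 ratio to uninduced cells of 2.96 at 3 days and -1.53 at 6 days. Ratios of Hspa1b were 2.61 and -1.09, and those of Hspb1 2.91 and -0.89. Socs2, a suppressor of cytokine signalling, went the other way, with -0.75 at 3 days and 0.67 at 6 days. These 4 genes are given because the induced libraries lay on opposite sides of the uninduced one, and the difference between them was not tested. In barcodes of 10 to 100 UMIs outside the cell sets, which no comparison uses, Rbpj stood at 291 CPM (235 to 357) at 3 days and 285 CPM (255 to 318) at 6 days, above 17.4 CPM (11.8 to 24.9) in control. Pf4 in those barcodes stood at 109 CPM at 6 days, above 2.32 CPM in control.

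The libraries paired as control with 6 days and uninduced with 3 days, with 14 genes, Hes1 included, at least 1.5-fold lower and 12 higher in the second pair, against 0 and 1, and 0 and 5 with Rbpj included, for the other pairings, while 16 lower and 17 higher genes (17 and 13 without other cell types) set the 3-day library apart from each of the others, and 25 and 4 the control library (11 and 4 without other cell types). Of 52 sequence-searched genes 1.5-fold lower in uninduced than in control cells, Hes1 and Rbpj apart, 42.3% (22 genes) had mostly shared ends, against a mean of 1.59 genes in matched random sets (at most 4 in the central 95% of them), so reads shared between near-identical transcripts may account for part of this group. Of 40 genes 1.5-fold higher in uninduced progenitors, 12 were dissociation and immediate early genes, against a mean of 0.155 in random sets (at most 1 in the central 95%), but that list had already been seen to be higher in this comparison, so the count decides nothing and a stress or handling response stays open. These groups did not follow the timing of Hes1, in values that put the pairing already seen into numbers, since at 3 days the lower genes had covered a median of 16.2% of their first step (12.9 to 22.8) and the higher genes 1.05% (-2.86 to 6.65), against 54.4% for Hes1 (47.8 to 60.7). A slower effect of RBPJ and a difference between library batches cannot be told apart with 1 library per group, and neither was tested.

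Within each induced library Hes1 was lower in thinned progenitor cells with 3 or more Rbpj UMIs than in those with none, at 16.5 CPM (9.78 to 26.1) against 45.8 CPM (38.3 to 54.4) at 3 days (ratio 0.360 (0.207 to 0.592)) and 71.9 CPM (59.6 to 86.1) against 161 CPM (149.8 to 173) at 6 days (ratio 0.446 (0.364 to 0.542)). In cells with 1 or 2 Rbpj UMIs Hes1 stood at 52.3 CPM (39.5 to 67.9) at 3 days and 159.7 CPM (141.6 to 179.5) at 6 days. Those intervals overlap the ones of cells with none, so Hes1 did not fall stepwise with Rbpj UMIs and only the highest class was lower. Uninduced progenitors thinned alike stood at 19.0 CPM (16.3 to 22.0), so at 3 days the cells with 3 or more Rbpj UMIs did not lie above them, and whether cells without a Rbpj UMI were induced was not decided, because cells that were not induced would be low in Hes1 and not high. Progenitor cluster was argued against as the whole cause within the clusters covered. At equal cluster makeup the ratio was 0.394 (0.286 to 0.528) at 6 days and 0.326 (0.145 to 0.580) at 3 days. It covered 4 and 3 clusters, those with at least 20 cells of each class. The stem cell-like cluster was left out. The 3-day ratio rests on 1, 4 and 6 Hes1 UMIs in the 3-or-more class. In cells with a mitotic gene UMI the ratios were 0.429 (0.334 to 0.546) and 0.347 (0.184 to 0.612) in the same order. The classes there still differed in depth, at 11596 (3 or more) against 9458 UMIs (none) at 6 days. These ratios do not decide on cell cycle stage, because a mitotic gene UMI does not fix the stage of a cell. Among cells without such a UMI the interval held 1 at both times, at 0.875 (0.594 to 1.25) and 0.389 (0.0782 to 1.19), as cell cycle stage would give, but the 3-day ratio rests on 3 Hes1 UMIs, and with a minimum of 10 UMIs, set after these values were seen, it stays open. No biological explanation was tested, because no group of the design differs in Rbpj level alone.

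Neutrophil genes were higher in each of the 3 other libraries than in control, with S100a8 at 495, 1653, 1962 and 1382 CPM in control, uninduced, 3-day and 6-day cells. The neutrophil-like cluster held at least 97.0% of the S100a8 UMIs in each of the 3, which is consistent with a few cells of another type in the sort, although an LMPP sort is meant to leave such cells out. Free RNA spread over all cells was argued against as the source of most of these UMIs, because at most 3.02% of S100a8 UMIs lay outside that cluster. It stays open for the small part in progenitors, where S100a8 stood at 11.3, 21.4, 34.0 and 26.5 CPM, since S100a8 in barcodes outside the cell sets was also lowest in control, at 663, 1665, 2138 and 1945 CPM. Whether RBPJ affects the number of such cells was not tested and cannot be told apart from a difference between sorts or library batches.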

How the results depend on the processing

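All alternatives were planned except leaving out other cell types and each gene's 10 highest cells, which were chosen after the data were seen. Hes1 and Rbpj kept their direction in every alternative run for uninduced against control, 3-day against uninduced and 6-day against uninduced cells, with log2 ratios of -2.62 to -2.04, 1.05 to 1.47 and 2.55 to 2.88 for Hes1 and -0.81 to -0.49, 3.70 to 5.40 and 3.42 to 5.42 for Rbpj. For single genes, 6260 values were compared, of which 5306 stayed within the counting interval, 930 moved and 24 changed sign from a ratio of at least 1.5-fold, a bound set after the values were seen. A further 47 sign changes were of ratios under 1.5-fold. List medians stayed within their interval in 1411 of 1716, moved in 284 and changed sign in 21. Gene counts stayed within 1.5 times in 97 of 120, reversal counts in 15 of 20, and shares within their interval in 117 of 192. TMM and DESeq2 scaling moved the median log2 ratio of all genes by at most 0.0939. The planned restriction to multipotent lymphoid-primed clusters was not run, because no cluster took that name. Depth limits genes near 2 CPM, above all at 3 days, the library with fewest UMIs.

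The following values changed sign, or answer a comparison and moved, with list members filtered anew in each setting, and the cause was not tested. Without other cell types, log2 ratios were Chil3 -0.15, Elane -0.000163 and B lineage genes -0.13 in uninduced against control, and Hba-a1 0.23 and erythroid genes 0.19 in 3-day against uninduced. The same setting gave Elane 0.0171, Pf4 -0.0581, Retnlg -0.31 and megakaryocyte genes -0.0292 in 6-day against 3-day, and Hba-a1 0.51, Hbb-bs 0.19 and myeloid progenitor genes -0.13 in 3-day against control. It also gave erythroid genes -0.00198 and megakaryocyte genes -0.0865 in 6-day against control. Counts there were 10 genes 2-fold higher in uninduced against control cells, 5 genes 2-fold lower in 3-day against uninduced cells, 5 genes 2-fold higher in 6-day against uninduced cells and 6 genes 2-fold higher in 6-day against control cells. Without each gene's 10 highest cells, log2 ratios were Cxcl10 -0.000529, Ifit1 -0.22, Ltf -0.56, mature neutrophil and monocyte genes -0.62 and integrated stress response genes -0.0215 in 3-day against uninduced, and Elane -0.0111 and mature neutrophil and monocyte genes -0.0868 in 6-day against uninduced. The same setting gave Camp 0.48 and mature neutrophil and monocyte genes 0.28 in 6-day against 3-day, and Hba-a1 0.34, Hbb-bs 0.14, B lineage genes -0.34 and myeloid progenitor genes -0.17 in 3-day against control. It also gave erythroid genes -0.0134 and megakaryocyte genes -0.15 in 6-day against control. In cells without mitotic gene UMIs, log2 ratios were Hes1 -2.62, Notch target genes -0.11 and core Notch target genes -0.35 in uninduced against control, and Hba-a1 0.58, Hes1 1.47, Rbpj 3.70 and erythroid genes 0.19 in 3-day against uninduced. The same setting gave Rbpj 3.42 and G2 and M phase genes -0.0889 in 6-day against uninduced, and Elane 3.33, Hba-a1 -0.50 and erythroid genes -0.0444 in 6-day against 3-day. It also gave Gm26737 0.25, Hba-a1 1.22 and Hbb-bs 0.12 in 3-day against control, and Dqx1 0.29 and megakaryocyte genes -0.16 in 6-day against control. Counts there were 13 genes 2-fold higher in uninduced against control cells, 24 genes 2-fold higher and 13 genes 2-fold lower in 3-day against uninduced cells, 16 genes 2-fold higher in 6-day against uninduced cells, 31 genes 2-fold higher in 6-day against 3-day cells, 35 genes 2-fold lower in 3-day against control cells, 1 gene 2-fold lower in 6-day against control cells, 6 reversal genes lower without RBPJ and 2 reversal genes higher without RBPJ. In thinned cells, log2 ratios were Notch target genes -0.0261 in 3-day against uninduced, and mature neutrophil and monocyte genes -0.0164 and G2 and M phase genes -0.0434 in 6-day against uninduced. The same setting gave Hba-a1 0.38 and Hbb-bs 0.0122 in 3-day against control, and megakaryocyte genes -0.0210 in 6-day against control. Counts there were 16 genes 2-fold higher in 3-day against uninduced cells, 5 reversal genes lower without RBPJ and 3 reversal genes higher without RBPJ. With a pseudocount of 5 CPM, log2 ratios were Hes1 -2.04 in uninduced against control, and Rbpj 4.98 in 3-day against uninduced. The same setting gave Hes1 2.55 and Rbpj 4.92 in 6-day against uninduced. Counts there were 5 genes 2-fold lower in uninduced against control cells, 5 genes 2-fold higher in 6-day against uninduced cells and 7 genes 2-fold higher in 6-day against 3-day cells. With the mean of single-cell CPM, log2 ratios were Rbpj 5.01 in 3-day against uninduced, and Rbpj 4.98 in 6-day against uninduced. Counts there were 14 genes 2-fold lower in 3-day against uninduced cells and 1 gene 2-fold lower in 6-day against control cells. Under the own cell filter there were 16 genes 2-fold higher in 3-day against uninduced cells. With no list filter and 30 CPM for gene counts, log2 ratios were Notch target genes 0.00 in 3-day against uninduced. Counts there were 4 genes 2-fold lower in uninduced against control cells, 4 genes 2-fold higher in 6-day against uninduced cells, 10 genes 2-fold higher in 6-day against 3-day cells, 7 genes 2-fold lower in 3-day against control cells, 13 genes 2-fold higher in 6-day against control cells and 0 reversal genes higher without RBPJ.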

Other observations

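The values in this part were chosen after the data were seen. In the induced libraries Rbpj differed widely between clusters. In the stem cell-like cluster, with Mecom and Hlf among its markers, Rbpj stood at 76.0 CPM (57.6 to 98.5) at 3 days and 83.0 CPM (70.7 to 96.8) at 6 days, and in the cluster marked by Ccr9 and Tmem158 at 29.7 CPM (18.4 to 45.4) at 3 days and 47.9 CPM (32.7 to 67.6) at 6 days. In the cluster led by S phase genes it stood at 645 CPM (613 to 678) at 3 days and 665 CPM (635 to 696) at 6 days, and in the cluster led by mitotic genes at 651 CPM (619 to 684) at 3 days and 710.3 CPM (683 to 738) at 6 days. In the cluster led by the histone gene Hist1h2bc it stood at 1266 CPM (1132 to 1412) at 3 days and 1221 CPM (1130 to 1316) at 6 days. Hes1 there stood at 97.7 and 279 CPM, above the library levels of 43.5 and 129 CPM. It was above the library level without induction too, at 158 against 89.7 CPM in control and 40.1 against 18.0 CPM in uninduced cells. Granulocyte-monocyte progenitor-like cells had 21.2 CPM in control, 33.6 CPM in uninduced, 1114 CPM in 3-day and 1110.5 CPM in 6-day cells. Megakaryocyte-erythroid-like cells had 1398 and 1527 CPM at 3 and 6 days. Neutrophil-like cells had 3533 CPM (3193 to 3899) at 3 days and 449.7 CPM (351 to 568) at 6 days, resting on 14 and 24 cells, of which the highest held 147 of 395 and 21 of 70 Rbpj UMIs. Early B-like cells had 1824 CPM (1222 to 2619.8) at 3 days and 6489.6 CPM (5917 to 7103) at 6 days, resting on 3 and 13 cells, of which the highest held 14 of 29 and 112 of 471 Rbpj UMIs.

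Several genes differed between progenitors with 3 or more Rbpj UMIs and those with none, within each induced library after thinning, and the ones named here were picked from those with the largest ratios. Before thinning the classes differed in depth, with medians of 10586 against 7598 UMIs at 3 days and 11036 against 7302 at 6 days. The cyclin gene Ccna2 stood at 122 against 43.7 CPM at 3 days and 110.0 against 42.1 CPM at 6 days, the proliferation marker Mki67 at 101 against 40.9 CPM at 3 days and 101 against 42.8 CPM at 6 days, the spindle checkpoint kinase gene Bub1b at 26.6 against 9.86 CPM at 3 days and 32.0 against 11.3 CPM at 6 days and Hmmr at 44.9 against 17.3 CPM at 3 days and 55.6 against 20.7 CPM at 6 days. Wfdc17 and Wfdc18 were lower, with Wfdc17 at 179 against 409.7 CPM at 3 days and 259 against 616 CPM at 6 days and Wfdc18 at 12.8 against 45.1 CPM at 3 days and 13.3 against 46.7 CPM at 6 days. A UMI of 7 mitotic genes was seen in 51.5% of 3-day cells without a Rbpj UMI and 84.1% of those with 3 or more, and in 48.2% and 87.5% at 6 days.

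Xist, transcribed from the inactive X chromosome of females, stood at 1109, 1204, 1066 and 1744 CPM in control, uninduced, 3-day and 6-day cells. The Y-linked genes Ddx3y and Eif2s3y stood at 29.2, 33.6, 30.6 and 20.6 CPM and at 36.7, 33.7, 38.9 and 23.4 CPM. Every library thus held Xist and Y-linked transcripts, with Xist highest and these Y-linked genes lowest at 6 days. Whether the libraries differed in sex makeup was not tested, which is a further limit on the 6-day comparisons. Hba-a1 in barcodes outside the cell sets stood at 98.2, 339.9, 241 and 266 CPM.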
